A study of Mus musculus with 12 samples.

How the data were processed

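Colon RNA was measured by RNA sequencing in 12 libraries, 3 per day of harvest. Per the labels, mice that were 7 weeks old and free of specific pathogens drank clean water or 3% dextran sulfate sodium (DSS), a sulfated polysaccharide that injures the colonic epithelium and causes colitis, for 6 days. The mid-colon was taken at days 0, 2, 4 and 6. The day of each library came from its time point label and its replicate number from its title. The labels name no water-drinking group at days 2, 4 and 6, so day 0 was the only reference, and the effect of DSS and that of the day of harvest, age included, cannot be told apart. Nothing in the labels says that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

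Per the labels' protocols, total RNA was extracted with TRIzol and poly(A) RNA was selected. The second cDNA strand carried dUTP and was removed with uracil-DNA glycosylase, and 8 rounds of amplification were run. Libraries with a mean insert of 300 bases were read as 150-base pairs on a NovaSeq sequencer. Reads were aligned to mm10 with HISAT2 2.2.1 and counted with featureCounts 2.0.1, per the submitters' processing notes. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may be shared, and near-identical paralogs may share reads too.

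The authors deposited 1 table of CPM (read counts scaled to a common library total) for 25904 gene symbols, with no further scaling. The columns summed to between 992026 and 998040 CPM, so 0.196% to 0.797% of each library's reads lay outside the listed genes. The table was tested for whole reads: in each library the low values were multiples of 1 read, and 100% of the values came within 0.1 of a whole number of reads. These gave 30979977 to 40930613 reads per library, so 1 read was worth well under 0.1 CPM. Floors for a gene with no reads were set at 3 reads over the 3 libraries of a day and cover counting error only, because amplified reads without molecular identifiers are not independent molecules. The tests, filters, gene lists, named-gene rule and most alternatives were chosen before the data were examined. They had assumed values normalized by size factors, and the thresholds foreseen for CPM were used once the unit was known. No column was left unmapped.

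Genes with at least 1 CPM in at least 3 libraries were tested, which kept 15246. The main test was limma 3.58.1 (R 4.3.3) on log2(CPM + 1), with the means of the 4 days and 1 residual variance fitted over the 12 libraries, empirical Bayes moderation with trend and robust settings, and Benjamini-Hochberg adjustment over the genes of each comparison with a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. An F test over the 4 days used the same fit. Days 2, 4 and 6 were each compared with day 0, day 4 with day 2, and day 6 with day 4. Unless stated otherwise, an adjusted p for a gene is from limma, fold changes carry their standard error (SE), and CPM values are mean ± SD over 3 libraries.

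A set of 51 gene lists was fixed, 24 of cell type markers and 27 of processes, with 929 symbols. Of these symbols, 13 mitochondrial genes were found under another name and 3 were absent from the table. Lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with the other genes, again with a correlation estimated per list, and with fry. The directional p of fry asks whether a list's genes move one way on balance and its mixed p whether they change in either direction, and neither compares the list with other genes. List p-values were adjusted over the lists of a comparison. List counts are given over all genes tested and also adjusted over the list alone. List scores per library are means of log2(CPM + 1).

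Named genes followed a fixed rule. Against day 0 these were the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the libraries of the 2 days, leaving out predicted or unnamed genes and immunoglobulin and T cell receptor segments. From each list, up to 4 members with the largest change in the direction of most members past the threshold were named, and up to 2 in the other direction. A panel of 20 genes was named at every day. In all, 339 genes met this rule, and the values of some of them are not reported here. Genes outside this rule are said to be chosen after their values were seen. Coordinates are those of GENCODE release M21 for GRCm38, the assembly also called mm10, in which 24732 of the 25904 symbols have a gene of that name.

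The alternatives were pseudocounts of 0.5 and 5, no filter on low values, a mean of at least 5 CPM, median-of-ratios scaling, quantile normalization, moderation without trend and robust, the replicate number as a block, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on the recovered reads, array weights, fits of only the 2 days compared, and each library left out in turn. A further 3 were chosen after seeing the data, namely leaving out day 0 replicate 1 together with day 6 replicate 2, rescaling without ribosomal and mitochondrial RNA, and array weights estimated gene by gene. The planned array weights stopped before converging, with a highest weight of 400 for 1 library, and were not used. Pairing of libraries by replicate number was also checked. The tests were run on data simulated from these libraries' means for day 6 against day 0, with 50 genes changed at each fold over 15246 genes. Limma recovered 1 of 50 genes changed 1.5-fold, 19 changed 2-fold, 49 changed 4-fold and 48 changed 8-fold, and 5 of its 122 calls were false. The edgeR test made 4 false calls of 126 and DESeq2 30 of 157. Far more genes, 5476, were called at day 6 in the real data, so these rates may not carry over. Of 30 lists without change, camera called 1, and its rate for lists whose genes vary together was not tested. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.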

Results

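Gene expression in mouse colon was followed over 6 days of colitis induced by 3% DSS in drinking water. The mid-colon was sampled at day 0 and at days 2, 4 and 6, with 3 libraries per day. The series asked how transcription in the colon changes over time as colitis develops. Of 25904 gene symbols, 15246 passed the filter on low values. A gene at 1 CPM rested on over 30 reads in each library.

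Libraries of the same day correlated across genes with r of 0.966 to 0.984 at day 0, 0.985 to 0.988 at day 2, 0.983 to 0.99 at day 4 and 0.914 to 0.978 at day 6. Correlations across genes within libraries do not treat genes as independent replicates. The first principal component held 63% of the variance and the second 15.7%, and the second set day 6 replicate 2 apart. That library had the highest smooth muscle score of day 6, 7.98 against 7.31 and 6.76 in the other libraries, and the lowest goblet cell score, 6.11 against 6.72 and 7.53. Markers of skeletal muscle, a tissue outside the mucosa, scored 3.98 in day 0 replicate 2 and 3.38 in day 6 replicate 1 against 0.82 in day 6 replicate 2. They also differed between days, with 2.44 to 3.06 at day 4 against 1.18 to 1.37 at day 2. That difference was 1.4 in the means (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The ribosomal RNA gene Rn45s took 0.34% to 5.57% of reads and mitochondrial genes 2.73% to 5.44%.

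Few genes passed the test at day 2, against 33.2% of those tested at day 4 and 35.9% at day 6. At day 2, 18 genes were higher and 31 lower than at day 0. At day 4, 3225 genes were higher and 1833 lower, of which 1401 and 841 differed by over 2-fold, and at day 6, 3585 were higher and 1891 lower, of which 1885 and 949 differed by over 2-fold. Day 4 differed from day 2 by 3207 higher and 1973 lower genes, and day 6 from day 4 by 289 and 145. The F test over the 4 days called 6550 genes, 43% of those tested. The excess of higher genes moved with scaling. At day 4, 63.8% of the changed genes were higher on CPM as deposited, against 49.7% with median-of-ratios scaling, 46.9% with quantile normalization and 49.6% in edgeR. At day 6 the share was 65.5%, against 51.1%, 46.5% and 53.9%, and from day 2 to day 4 it was 61.9%, against 52.7%, 48.6% and 53.2%. The median log2 fold change of all genes was 0.043 at day 2, 0.135 at day 4 and 0.137 at day 6. It was 0.073 from day 2 to day 4 and 0.031 from day 4 to day 6, and the medians of gene lists are given relative to it.

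**Figure D1:**
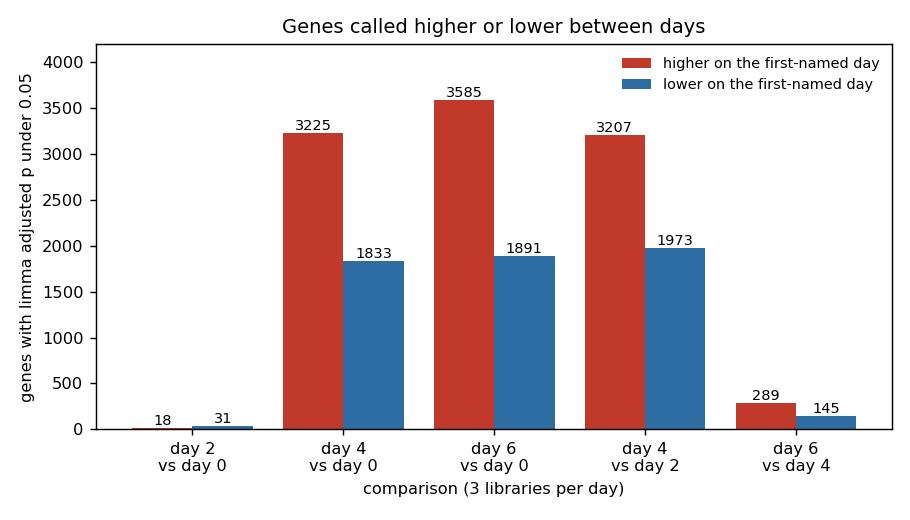
Number of genes higher and lower in each comparison of days (bars, limma, adjusted p under 0.05, 15246 genes tested, 3 libraries per day). Bars for day 4 against day 0 stand at 3225 and 1833 genes, against 18 and 31 for day 2 against day 0.

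Day 2 was compared with day 0 early in exposure. Genes of cholesterol synthesis fell. Mvd, which makes isopentenyl diphosphate, fell from 164 ± 35.9 to 42.9 ± 2.96 CPM (log2 fold change -1.89 ± 0.18, adjusted p = 0.00233), and Lss, lanosterol synthase, from 115 ± 3.21 to 35 ± 4.93 CPM (-1.69 ± 0.12, adjusted p = 0.000213). Insig1, the sterol-sensing regulator of this pathway, fell from 368 ± 80.2 to 97.2 ± 4.56 CPM (-1.89 ± 0.24, adjusted p = 0.00664). Hmgcs1, an early synthase of the pathway, fell from 694 ± 46.9 to 212 ± 49.5 CPM (-1.73 ± 0.22, adjusted p = 0.00664). Zbtb16, a transcription factor induced by glucocorticoids, rose from 1.9 ± 0.711 to 32.2 ± 3.31 CPM (3.54 ± 0.43, adjusted p = 0.00664), and the clock gene Arntl rose from 20.7 ± 2.91 to 56.6 ± 3.11 CPM (1.41 ± 0.16, adjusted p = 0.00424).

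Of the 22 genes tested for cholesterol synthesis, 12 were lower (20 adjusted over the list alone), with a median of -1.27 relative to all genes (camera adjusted p = 3.32e-31, adjusted p = 0.159 with an estimated correlation, fry adjusted p = 0.00737). Other falls at day 2 were Scd2, a fatty acid desaturase (-1.77 ± 0.27), Rdh9 (-1.58 ± 0.28), Acat2, which condenses acetyl-CoA (-1.54 ± 0.17), and Msmo1, a sterol demethylase (-1.51 ± 0.22), with adjusted p of at most 0.0418. Rises were Ffar4, a fatty acid receptor (2.15 ± 0.31), Pdk4, which restrains pyruvate oxidation (1.94 ± 0.32), Sgk1, an ion transport kinase (1.57 ± 0.25), and Abcb1a, a drug efflux pump (1.45 ± 0.22). Adra2a (1.41 ± 0.23) and Kbtbd11 (1.10 ± 0.12) rose too, all with adjusted p of at most 0.0315. The glucocorticoid response list had 4 of 14 members higher (5 adjusted over the list alone), namely Zbtb16, Pdk4, Sgk1 and Fkbp5 (1.07 ± 0.14). Its median was 0.62 relative to all genes (camera adjusted p = 2.93e-05, adjusted p = 0.551 with an estimated correlation). Of 17 circadian clock genes, Arntl was higher and Bhlhe41 (-1.43 ± 0.24) and Ciart (-1.34 ± 0.24) were lower (5 and 5 adjusted over the list alone), and camera made no call (adjusted p = 0.609). The mixed test of fry for change in either direction gave an adjusted p of 0.000269 for the clock list.

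Camera called 17 lists at day 2, most of them with no single gene past the threshold, and none with an estimated correlation. Of 26 proliferation genes none passed by limma (13 lower at an unadjusted p under 0.05), against 8 lower adjusted over the list alone, and their median was -0.9 relative to all genes (camera adjusted p = 2.52e-12, adjusted p = 0.616 with an estimated correlation). Plasma cell genes had 1 of 10 lower (7 adjusted over the list alone), Tnfrsf17, the BCMA receptor (-1.05 ± 0.16, adjusted p = 0.0196), and a median of -1.26 (camera adjusted p = 9.44e-07, adjusted p = 0.551 with an estimated correlation). B cell genes had none past the threshold (4 lower at an unadjusted p under 0.05, 3 lower adjusted over the list alone) and a median of -0.4 (camera adjusted p = 9.19e-05, adjusted p = 0.159 with an estimated correlation). Among 18 stromal fibroblast genes, Gli1, a hedgehog effector, was lower (-1.49 ± 0.22, adjusted p = 0.0156) and camera made no call (adjusted p = 0.769). Immediate early and dissection-related genes had none past the threshold (9 higher at an unadjusted p under 0.05, 7 higher adjusted over the list alone) and a median of 0.49 (camera adjusted p = 2.83e-06, adjusted p = 0.159 with an estimated correlation). Of the gut wall, smooth muscle (adjusted p = 0.017), enteric neuron and glia (0.0127) and collagen and matrix genes (0.00266) were called up by camera, each at 0.867 with an estimated correlation. Enteroendocrine (0.0336, 0.555 with an estimated correlation) and NF-kB and TNF feedback genes (0.044, 0.867 with an estimated correlation) were called up too. Called down were antimicrobial and mucosal defence (3.11e-05) and stem cell and crypt base genes (0.00639), both at 0.551 with an estimated correlation. Respiratory chain (6.57e-06), interferon response (0.00451) and unfolded protein response genes (0.0153) were also called down, all at 0.867 with an estimated correlation. No member of these 10 lists passed by limma, with 14 higher and 20 lower at an unadjusted p under 0.05, and 1 higher and 10 lower adjusted over the list alone. Without day 0 replicate 2 camera's adjusted p was 0.249 for the enteroendocrine list, 0.114 for stem cells, 0.0939 for smooth muscle and for enteric neurons and glia, 0.0935 for NF-kB and TNF feedback and 0.196 for the unfolded protein response. The interferon call was lost without day 0 replicate 3 (0.618), day 2 replicate 2 (0.06) or day 2 replicate 3 (0.058). The enteroendocrine call was also lost without day 0 replicate 3 (0.103) or day 2 replicate 1 (0.0592) and that of smooth muscle without day 2 replicate 1 (0.0592). NF-kB and TNF feedback lost it without day 0 replicate 1 (0.0994), day 2 replicate 1 (0.201) or day 6 replicate 2 (0.0545) as well. None of the 20 panel genes passed at day 2. Il1b stood at 1.03 ± 0.31 against 0.726 ± 0.18 CPM (0.23 ± 0.28, adjusted p = 0.695) and Lcn2 at 2.45 ± 0.376 against 2.43 ± 0.518 CPM (adjusted p = 0.992). Lgr5 stood at 2.35 ± 0.985 against 7.17 ± 1.39 CPM (-1.32 ± 0.32, adjusted p = 0.122).

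The day 2 counts rested on single libraries. They were 206 higher and 351 lower without day 6 replicate 2, which enters only through the shared variance, and 36 and 49 without day 6 replicate 3. Without replicates 1, 2 and 3 of day 0 they were 10 and 22, 4 and 10, and 5 and 12. Without replicates 1, 2 and 3 of day 2 they were 10 and 10, 4 and 9, and 7 and 14. The 31 lower genes became 20 without day 4 replicate 1 and 18 without day 4 replicate 3. Without day 6 replicate 2, 20 cholesterol genes, 20 proliferation genes, 6 plasma cell genes and 2 B cell genes were lower and 4 immediate early genes higher, and 5 stem cell and 3 antimicrobial genes lower. Cholesterol genes were lower in 6, 4 and 6 cases without replicates 1, 2 and 3 of day 0 and in 5, 5 and 7 without those of day 2. The 4 glucocorticoid genes became 1 or 2 without each library except day 0 replicate 1, day 6 replicate 2 and day 6 replicate 3. Zbtb16, Arntl, Kbtbd11, Mvd, Insig1, Lss and Acat2 kept their calls in all 12 such fits. Of the 21 genes named at day 2, 14 lost theirs without day 0 replicate 2. Without day 2 replicate 2 the adjusted p was 0.171 for Pdk4, 0.192 for Adra2a, 0.0937 for Ffar4 and Abcb1a and 0.132 for Scd2. There it was also 0.207 for Rdh9 and Bhlhe41, 0.21 for Ciart, 0.106 for Msmo1, 0.131 for Tnfrsf17 and 0.0731 for Fkbp5. Those of Sgk1 (0.134 without day 2 replicate 3), Gli1 (0.0702 without day 0 replicate 1) and Hmgcs1 (0.0509 without day 0 replicate 2) were lost too. DESeq2 called 190 higher and 350 lower genes and edgeR 13 and 22.

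Day 4 was compared with day 0 in the middle of the course. Interferon-induced genes and chemokines rose and genes of goblet cells and xenobiotic metabolism fell. Cxcl10, a chemokine that attracts T cells, rose from 2.21 ± 0.858 to 324 ± 26.5 CPM (6.70 ± 0.33, adjusted p = 3.64e-07), and Mmp3, stromelysin 1, from 1.57 ± 0.135 to 244 ± 39.1 CPM (6.56 ± 0.35, adjusted p = 6.08e-07). The antimicrobial lectin Reg3b rose from 69.8 ± 101 to 4830 ± 2290 CPM (7.27 ± 1.11, adjusted p = 0.000555) and its neighbour Reg3g from 27.9 ± 39.3 to 2040 ± 1090 CPM (7.05 ± 1.05, adjusted p = 0.000475). Ang4, an antimicrobial ribonuclease of goblet and Paneth cells, fell from 1490 ± 829 to 16.1 ± 5.17 CPM (-6.29 ± 0.45, adjusted p = 2.85e-06). Cyp2c55, a colonic cytochrome P450, fell from 1090 ± 492 to 33.8 ± 16.9 CPM (-5.00 ± 0.43, adjusted p = 1.15e-05). Of 22 antimicrobial and mucosal defence genes 10 were higher and 4 lower (11 and 4 adjusted over the list alone), and camera made no call (adjusted p = 0.269).

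All 35 genes of the interferon response list rose at day 4 (35 adjusted over the list alone), with a median of 3.3 relative to all genes (camera adjusted p = 8.53e-24, adjusted p = 0.346 with an estimated correlation). The largest rises were those of the interferon-inducible GTPases Iigp1 (6.70 ± 0.46), Gbp5 (5.82 ± 0.24), Tgtp1 (5.61 ± 0.43) and Gbp2 (5.27 ± 0.29), with adjusted p of at most 4.8e-06. Ido1, the interferon-induced enzyme of tryptophan breakdown, rose by 6.18 ± 0.40 (adjusted p = 1.44e-06). Of 28 cytokines and chemokines, 26 rose and Ccl28 fell (-1.77 ± 0.45, adjusted p = 0.0106), the same numbers adjusted over the list alone, with a median of 2.2 (camera adjusted p = 3.6e-14, adjusted p = 0.313 with an estimated correlation). The neutrophil attractant Cxcl5 rose by 6.03 ± 0.25, Cxcl9 by 6.03 ± 0.39 and the monocyte attractant Ccl2 by 5.32 ± 0.21, with adjusted p of at most 1.44e-06. Neutrophil markers rose in 13 of 14 cases (13 adjusted over the list alone) with a median of 2.75 (camera adjusted p = 7.57e-09, adjusted p = 0.346 with an estimated correlation). S100a9 (5.30 ± 0.37, adjusted p = 2.38e-06), Ly6g (4.63 ± 0.58, adjusted p = 0.000145) and Csf3r (4.38 ± 0.19, adjusted p = 1.36e-07) were among them. Monocyte and macrophage markers rose in 15 of 23 cases (16 adjusted over the list alone). Clec4e (3.71 ± 0.25), the high-affinity IgG receptor Fcgr1 (3.63 ± 0.22) and Ccr2 (3.41 ± 0.25) were among them, and camera gave adjusted p = 3.46e-06 (adjusted p = 0.36 with an estimated correlation).

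Feedback genes of NF-kB and TNF signalling rose in 15 of 19 cases (16 adjusted over the list alone). Socs3 stood at 3.73 ± 0.29 and Icam1 at 2.82 ± 0.16, and camera gave adjusted p = 4.12e-07 (adjusted p = 0.346 with an estimated correlation). Complement genes rose in 14 of 15 cases (14 adjusted over the list alone). C3 stood at 2.98 ± 0.53 (adjusted p = 0.00142), and camera gave adjusted p = 2.92e-06 (adjusted p = 0.36 with an estimated correlation). Matrix proteases and their inhibitors had 18 of 22 genes higher and Mmp15 lower (19 and 1 adjusted over the list alone). Mmp10 (4.94 ± 0.29), the collagenase Mmp13 (4.77 ± 0.26) and Timp1, an inhibitor of metalloproteases (4.40 ± 0.26) were among them, and camera gave adjusted p = 1.22e-08 (adjusted p = 0.346 with an estimated correlation). Mmp15 changed by -0.70 ± 0.19 (adjusted p = 0.0168). Collagen and matrix genes rose in 17 of 25 cases (17 adjusted over the list alone). Vcan, versican, stood at 2.26 ± 0.35 (adjusted p = 0.000578), and camera gave adjusted p = 0.0022 (adjusted p = 0.695 with an estimated correlation). Endothelial genes rose in 7 of 16 cases (7 adjusted over the list alone). The adhesion molecules Selp (3.95 ± 0.46), Vcam1 (2.67 ± 0.23) and Sele (2.13 ± 0.41) were among them, and camera gave adjusted p = 0.0081 (adjusted p = 0.695 with an estimated correlation). Regenerative epithelium genes had 13 of 21 higher and 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 4.27e-05, adjusted p = 0.346 with an estimated correlation). Ereg rose by 4.59 ± 0.54, Ly6a by 4.10 ± 0.26 and Il11 by 3.94 ± 0.38, and Krt17 fell (-2.61 ± 0.28, adjusted p = 4.49e-05). In whole tissue the list's rises at days 4 and 6 need not come from epithelium. Grem1 (3.77 ± 0.41) and Rspo3 (2.65 ± 0.34), stromal signals to the crypt, rose. Of the 18 stromal fibroblast genes 6 were higher and 3 lower (8 and 3 adjusted over the list alone), and camera made no call (adjusted p = 0.304). The 17 collagen and matrix genes became 6 without day 0 replicate 1, 8 without replicate 3 of day 0 or day 4, and 3 without day 4 replicate 2. The 7 endothelial genes became 4 without day 0 replicate 1 or day 4 replicate 2.

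Of 17 goblet cell genes 9 were lower at day 4 (12 adjusted over the list alone), with a median of -1.17 (camera adjusted p = 1.87e-06, adjusted p = 0.346 with an estimated correlation). The secreted mucus protein Clca1 (-4.07 ± 0.45, adjusted p = 5.76e-05), Best2 (-3.36 ± 0.45) and Spink4 (-2.47 ± 0.36) fell. The mucin Muc2 stood at 8770 ± 1310 against 13700 ± 3840 CPM (-0.62 ± 0.30, adjusted p = 0.136) and Tff3 at 362 ± 43.1 against 476 ± 97.1 CPM (adjusted p = 0.347). Of 33 xenobiotic metabolism genes 22 were lower and none higher (24 adjusted over the list alone), with a median of -1.5 (camera adjusted p = 1.77e-13, adjusted p = 0.346 with an estimated correlation). The sulfotransferase Sult1a1 (-4.77 ± 0.24, adjusted p = 3.62e-07) and the carboxylesterase Ces2a (-3.21 ± 0.47, adjusted p = 0.000424) were among them. Ion and water transport had 15 of 25 genes lower and Atp12a higher (16 and 1 adjusted over the list alone). Aqp1 (-2.07 ± 0.27, adjusted p = 0.000174) and the chloride exchanger Slc26a3 (-1.16 ± 0.29, adjusted p = 0.0114) were among them, and camera gave adjusted p = 2.98e-07 (adjusted p = 0.346 with an estimated correlation). Fatty acid and ketone oxidation had 13 of 29 genes lower and Acadl higher (15 and 1 adjusted over the list alone). Ppara stood at -1.69 ± 0.21, and camera gave adjusted p = 4.12e-07 (adjusted p = 0.412 with an estimated correlation). The 13 lower genes of fatty acid and ketone oxidation became 20 without day 6 replicate 2, and the 15 of ion and water transport became 8 without day 4 replicate 2. Cholesterol synthesis was lower in 15 of 22 genes (17 adjusted over the list alone), 11 of them among the 12 lower at day 2, with a median of -1.01 (camera adjusted p = 4.87e-09, adjusted p = 0.36 with an estimated correlation).

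Other large falls at day 4 were those of Mptx1, a mucosal pentraxin (-7.88 ± 1.22, adjusted p = 0.000605), the intelectin Itln1 (-5.23 ± 0.66, adjusted p = 0.00016) and Acer1, an alkaline ceramidase (-3.82 ± 0.41, adjusted p = 5.22e-05). Mptx1 already ranged from 1613 to 9085 CPM between the day 0 libraries. Clca4b rose by 6.24 ± 0.58 (adjusted p = 1.83e-05) and the acute phase gene Saa3 from 3.72 ± 3.01 to 327 ± 116 CPM (6.31 ± 0.64, adjusted p = 3.33e-05). Plasma cell genes fell in 8 of 10 cases (10 adjusted over the list alone). The immunoglobulin joining chain Jchain stood at -3.55 ± 0.45 and Mzb1 at -3.21 ± 0.45, and camera gave adjusted p = 8.34e-08 (adjusted p = 0.346 with an estimated correlation). Tuft cell genes had 7 of 12 lower and 1 higher (7 and 1 adjusted over the list alone). The channel Trpm5 (-1.14 ± 0.18, adjusted p = 0.000607) was among them, and camera gave adjusted p = 0.000362 (adjusted p = 0.346 with an estimated correlation). Smooth muscle genes had 4 of 16 lower (4 adjusted over the list alone). Actg2 (-1.77 ± 0.25, adjusted p = 0.000348) was among them, and camera gave adjusted p = 0.0046 (adjusted p = 0.626 with an estimated correlation). The count was 8 lower and 2 higher without day 6 replicate 2, 7 lower without day 6 replicate 3, and 2 lower without day 0 replicate 3 or day 4 replicate 1. Proliferation genes rose in 7 of 26 cases (7 adjusted over the list alone). Mcm4 stood at 1.17 ± 0.16 (adjusted p = 0.00028), and camera gave adjusted p = 0.011 (adjusted p = 0.74 with an estimated correlation). That count was 21 without day 6 replicate 2 and 3 or 4 without any library of day 0 or day 4, and camera's adjusted p was 0.0549 without day 4 replicate 1. Mki67 stood at 250 ± 71 against 160 ± 48.5 CPM (0.65 ± 0.45, adjusted p = 0.286).

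In the panel at day 4, Il1b rose to 68.4 ± 19 CPM (5.30 ± 0.28, adjusted p = 5.96e-07) and S100a8 to 21 ± 6.03 CPM (4.33 ± 0.43, adjusted p = 2.87e-05). Lcn2 rose to 45.5 ± 11.7 CPM (3.74 ± 0.45, adjusted p = 0.000111) and Cxcl1 to 24.9 ± 4.37 CPM (4.34 ± 0.37, adjusted p = 1.03e-05). Il6, with 1 read at day 0, 0 reads at day 2 and a floor of 0.0268 CPM there, reached 10.2 ± 3.06 CPM (adjusted p = 1.2e-05). Lgr5, the marker of crypt stem cells, fell to 1.53 ± 0.725 CPM (-1.71 ± 0.32, adjusted p = 0.00192). The water channel Aqp8 fell to 134 ± 71.9 CPM (-1.61 ± 0.52, adjusted p = 0.0352), a call lost in 4 of the 12 fits that left out a library (adjusted p = 0.134 without day 4 replicate 2). Car1 at 702 ± 185 against 1280 ± 505 CPM (adjusted p = 0.152), Acta2 at 978 ± 227 against 1420 ± 296 CPM (adjusted p = 0.195) and Cldn2 at 107 ± 28.4 against 104 ± 14.4 CPM (adjusted p = 0.997) did not pass. Of the 197 genes named at this day, 155 kept their call in every such fit. The call of Slc26a3 was lost without day 4 replicate 2 (adjusted p = 0.0528) and that of Atp12a in 2 fits (0.0951 without day 0 replicate 3), and the call of Mmp15 in 3 (0.0582 without day 0 replicate 2).

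**Figure D2:**
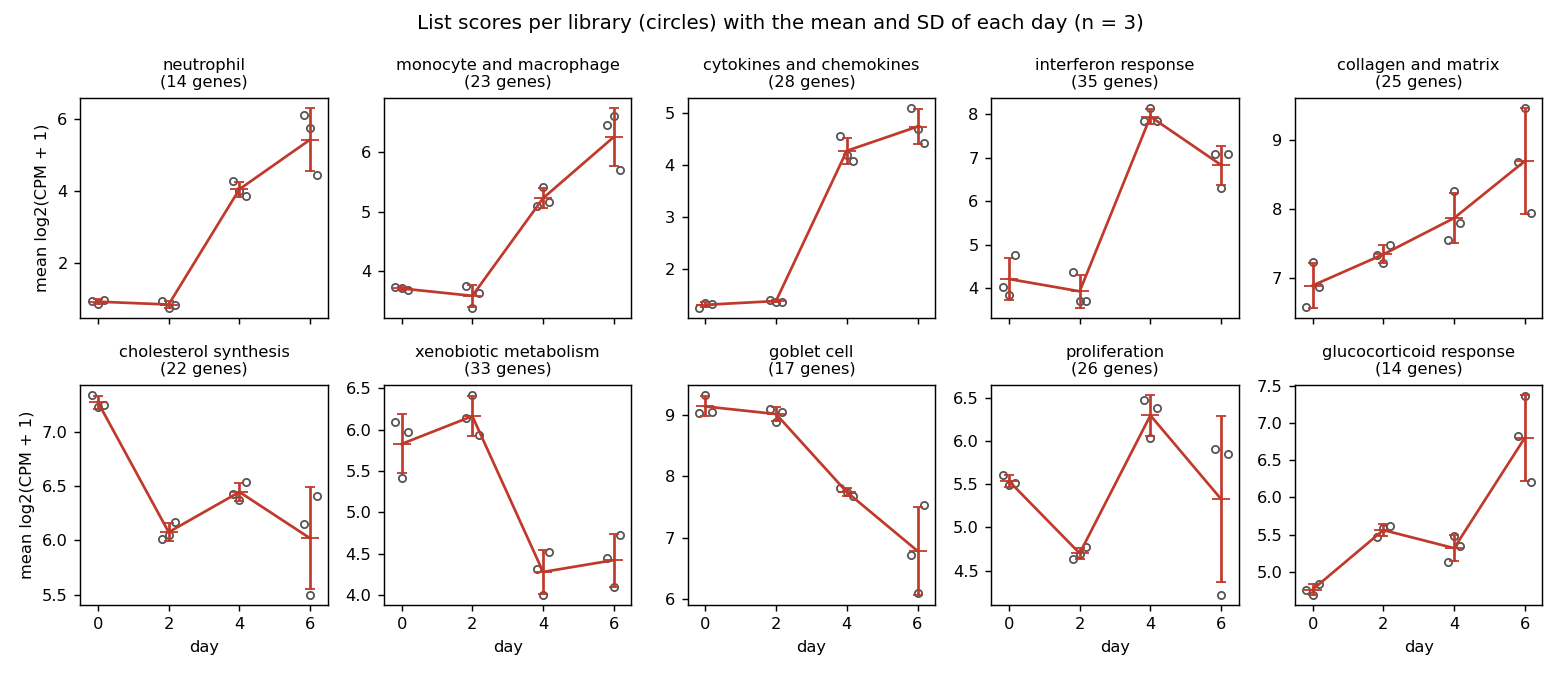
Mean log2(CPM + 1) of the members of 10 gene lists (y axis) by day (x axis), with circles for the 3 libraries of a day and lines for the mean ± SD. The neutrophil score rose from 0.93 at day 0 to 4.05 at day 4 and 5.44 at day 6, and the goblet cell score went from 9.13 to 7.74 and 6.79.

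Day 6 was compared with day 0 at the end of the exposure. Neutrophil genes rose and goblet cell genes fell. Saa3, an acute phase gene, reached 2790 ± 1790 CPM (9.13 ± 0.64, adjusted p = 1.66e-06) and Lcn2, lipocalin 2, which withholds iron from bacteria, 662 ± 395 CPM against 2.43 ± 0.518 CPM (7.34 ± 0.45, adjusted p = 6.57e-07). S100a8 and S100a9, the subunits of calprotectin, rose by 6.62 ± 0.43 (adjusted p = 9.72e-07) and 6.82 ± 0.37 (adjusted p = 2.99e-07). Clca1 fell from 19900 ± 8340 to 405 ± 178 CPM (-5.60 ± 0.45, adjusted p = 4.27e-06) and Muc2 from 13700 ± 3840 to 2060 ± 837 CPM (-2.77 ± 0.30, adjusted p = 4.23e-05).

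All 14 neutrophil markers rose at day 6 (14 adjusted over the list alone), with a median of 4.32 (camera adjusted p = 1.61e-11, adjusted p = 0.24 with an estimated correlation). The collagenase Mmp8 (6.12 ± 0.47, adjusted p = 3.02e-06) and the decoy receptor Il1r2 (5.52 ± 0.32, adjusted p = 4.86e-07) were among them. Monocyte and macrophage markers had 22 of 23 higher and Cx3cr1 lower, the same numbers adjusted over the list alone (camera adjusted p = 2.34e-11, adjusted p = 0.24 with an estimated correlation). Chil3 rose by 7.81 ± 0.57 (adjusted p = 2.03e-06) and Clec4e by 5.29 ± 0.25 (adjusted p = 1.63e-07), and Cx3cr1 changed by -0.76 ± 0.23 (adjusted p = 0.0241, and 0.0865 without day 6 replicate 1). T cell genes rose in 16 of 19 cases (18 adjusted over the list alone). The granzymes Gzmb and Gzma stood at 4.92 ± 0.25 and 3.56 ± 0.31 and Cd8a at 2.30 ± 0.32, and camera gave adjusted p = 3.33e-07 (adjusted p = 0.247 with an estimated correlation). Genes of MHC class II presentation rose in 8 of 10 cases (8 adjusted over the list alone). The transactivator Ciita (2.28 ± 0.36, adjusted p = 0.000609) was among them, and camera gave adjusted p = 0.000604 (adjusted p = 0.352 with an estimated correlation). Interferon response genes were higher in 28 of 35 cases (28 adjusted over the list alone) with a median of 2.55 (camera adjusted p = 1.09e-12, adjusted p = 0.247 with an estimated correlation), with Iigp1 at 6.53 ± 0.46 and Gbp4 at 5.16 ± 0.30. Cytokines and chemokines had 26 of 28 higher and Ccl28 lower (26 and 1 adjusted over the list alone). Cxcl5 (6.81 ± 0.25, adjusted p = 6.65e-08), Cxcl9 (6.42 ± 0.39) and Il1b (6.12 ± 0.28) were among them, and camera gave adjusted p = 2.21e-14 (adjusted p = 0.24 with an estimated correlation). Haptoglobin, Hp, rose by 7.26 ± 0.43 (adjusted p = 5.16e-07) and Ido1 by 6.92 ± 0.40 (adjusted p = 4.4e-07).

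Matrix genes stood higher at day 6. Collagen and matrix genes rose in 22 of 25 cases (23 adjusted over the list alone). The crosslinking enzyme Lox stood at 3.79 ± 0.43 and Thbs1 at 2.69 ± 0.52, and camera gave adjusted p = 1.7e-07 (adjusted p = 0.414 with an estimated correlation). Matrix proteases and inhibitors had 19 of 22 higher and Mmp15 lower (19 and 1 adjusted over the list alone). Mmp3 (7.46 ± 0.35, adjusted p = 1.56e-07) was among them, and camera gave adjusted p = 2.34e-11 (adjusted p = 0.24 with an estimated correlation). Complement genes rose in 13 of 15 cases (14 adjusted over the list alone). C3 stood at 4.80 ± 0.53, and camera gave adjusted p = 7.78e-08 (adjusted p = 0.247 with an estimated correlation). NF-kB and TNF feedback genes rose in 16 of 19 cases (16 adjusted over the list alone). Cebpd stood at 3.56 ± 0.35, and camera gave adjusted p = 4.75e-09 (adjusted p = 0.24 with an estimated correlation). Endothelial genes rose in 11 of 16 cases (12 adjusted over the list alone). Selp stood at 5.09 ± 0.46, and camera gave adjusted p = 3.33e-05 (adjusted p = 0.421 with an estimated correlation). Stromal fibroblast genes had 9 of 18 higher and 2 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.0305, adjusted p = 0.595 with an estimated correlation). Grem1 rose by 4.16 ± 0.41 and Gli1 fell (-2.20 ± 0.22, adjusted p = 1.96e-05), and camera's adjusted p for this list was 0.113 without day 6 replicate 2, and 14 were higher without day 6 replicate 3. Glucocorticoid response genes rose in 10 of 14 cases (12 adjusted over the list alone; camera adjusted p = 4.53e-05, adjusted p = 0.247 with an estimated correlation). Among them were Lcn2 and the metallothionein Mt2 (4.29 ± 0.39), which also respond to inflammation and metals, Zbtb16 (4.18 ± 0.43) and the phosphatase Dusp1 (2.36 ± 0.24). Glycolysis and hypoxia genes had 13 of 20 higher and Pfkfb4 lower (13 and 1 adjusted over the list alone). Pfkfb3 stood at 3.30 ± 0.30 and the lactate exporter Slc16a3 at 2.45 ± 0.16, and camera gave adjusted p = 0.00477 (adjusted p = 0.247 with an estimated correlation).

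Lists of secretory and crypt base cells and of epithelial metabolism were lower at day 6. Goblet cell genes fell in 16 of 17 cases (16 adjusted over the list alone), with a median of -2.46 (camera adjusted p = 7.48e-12, adjusted p = 0.24 with an estimated correlation), including Spink4 (-3.83 ± 0.36) and Fcgbp (-3.66 ± 0.56). Mucin and glycosylation genes had 15 of 24 lower and Gcnt1 higher (15 and 1 adjusted over the list alone). B3gnt6, which extends mucin O-glycans, stood at -3.64 ± 0.23, and camera gave adjusted p = 2e-07 (adjusted p = 0.247 with an estimated correlation). Tuft cell genes had 9 of 12 lower and 2 higher, Ptgs1 among them (9 and 2 adjusted over the list alone). Trpm5 (-3.83 ± 0.18, adjusted p = 1.28e-07) was among them, and camera gave adjusted p = 1.21e-05 (adjusted p = 0.24 with an estimated correlation). Enteroendocrine genes fell in 9 of 16 cases (9 adjusted over the list alone). The hormones Insl5 stood at -3.48 ± 0.68, Gcg at -2.36 ± 0.27 and Pyy at -1.99 ± 0.30, and camera gave adjusted p = 2.37e-05 (adjusted p = 0.24 with an estimated correlation). Stem cell and crypt base genes had 7 of 18 lower and 2 higher (7 and 2 adjusted over the list alone). Lgr5 stood at 0.884 ± 0.76 CPM (-2.18 ± 0.32, adjusted p = 0.00034), and camera gave adjusted p = 0.000541 (adjusted p = 0.24 with an estimated correlation). Xenobiotic metabolism genes fell in 20 of 33 cases (25 adjusted over the list alone; camera adjusted p = 2.89e-12, adjusted p = 0.24 with an estimated correlation). Cholesterol synthesis genes fell in 20 of 22 (21 adjusted over the list alone; camera adjusted p = 1.1e-13, adjusted p = 0.24 with an estimated correlation). Insig1 stood at -2.14 ± 0.24 and Tm7sf2 at -1.81 ± 0.20. Ion and water transport had 16 of 25 genes lower and Atp12a higher (16 and 1 adjusted over the list alone). The sodium channel subunit Scnn1a (-2.21 ± 0.33, adjusted p = 0.000425) was among them, and camera gave adjusted p = 9.38e-08 (adjusted p = 0.242 with an estimated correlation). Fatty acid and ketone oxidation had 16 of 29 lower and 2 higher (18 and 2 adjusted over the list alone). Acsm3 stood at -2.06 ± 0.24, and camera gave adjusted p = 1.7e-07 (adjusted p = 0.322 with an estimated correlation). The count was 9 lower without day 6 replicate 2, 7 without day 0 replicate 1, and 10 without day 0 replicate 3 or day 6 replicate 1. Absorptive colonocyte genes went both ways, 3 of 22 higher and 5 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.0428, adjusted p = 0.556 with an estimated correlation). That call was lost without day 0 replicate 1 (0.0721), day 0 replicate 3 (0.105), day 6 replicate 1 (0.0853) or day 6 replicate 2 (0.188). The 5 lower genes became 3 without day 6 replicate 1 or 2 and 8 without day 6 replicate 3. Regenerative epithelium genes had 14 of 21 higher and 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 0.000604, adjusted p = 0.247 with an estimated correlation), and 9 were higher without day 0 replicate 3 or day 6 replicate 1. Antimicrobial and mucosal defence genes had 9 of 22 higher and 6 lower (10 and 8 adjusted over the list alone), and camera made no call (adjusted p = 0.978).

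Other large falls at day 6 were Mptx1 (-9.53 ± 1.22, adjusted p = 0.000131), Ang4 (-7.93 ± 0.45, adjusted p = 4.26e-07) and Itln1 (-5.24 ± 0.66, adjusted p = 0.000123). Also lower were the pancreas-type secretory genes Sycn (-4.91 ± 0.39, adjusted p = 4.35e-06) and Clps (-4.88 ± 0.37, adjusted p = 2.8e-06), Pla2g4c (-4.45 ± 1.14, adjusted p = 0.0111) and the gasdermin Gsdmc3 (-4.41 ± 0.57, adjusted p = 0.000141). Pla2g4c ranged from 5.7 to 386 CPM between the day 0 libraries. In the panel, Tff3 fell to 204 ± 98.4 CPM (-1.31 ± 0.30, adjusted p = 0.00549) and Aqp8 to 75.1 ± 54.3 CPM (-2.53 ± 0.52, adjusted p = 0.00335). Il1b reached 126 ± 52.7 CPM (adjusted p = 1.3e-07), Il6 11.5 ± 5.15 CPM (adjusted p = 6.67e-06) and Cxcl1 53 ± 29.6 CPM (adjusted p = 1.77e-06). Timp1 reached 99.3 ± 34.9 CPM (adjusted p = 2.31e-07) and Ly6a 1110 ± 262 CPM (adjusted p = 1.9e-06). Reg3b stood at 3060 ± 2130 CPM (6.34 ± 1.11, adjusted p = 0.00116) and Reg3g at 936 ± 779 CPM (5.48 ± 1.05, adjusted p = 0.0021). Car1 at 1170 ± 91.9 CPM (adjusted p = 0.937), Slc26a3 at 357 ± 124 CPM (adjusted p = 0.295) and Mki67 at 135 ± 71.8 CPM (adjusted p = 0.532) did not pass against day 0. Neither did Acta2 at 1090 ± 470 CPM (adjusted p = 0.267) or Cldn2 at 111 ± 89.8 CPM (adjusted p = 0.55). Of the 198 genes named at day 6, 172 kept their call whichever library was left out. Atp12a lost it in 6 of the 12 fits (adjusted p = 0.162 without day 0 replicate 3), and Ptgs1 (0.062 without day 0 replicate 1) and Gcnt1 (0.0541 without day 0 replicate 3) in 1 each.

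**Figure D3:**
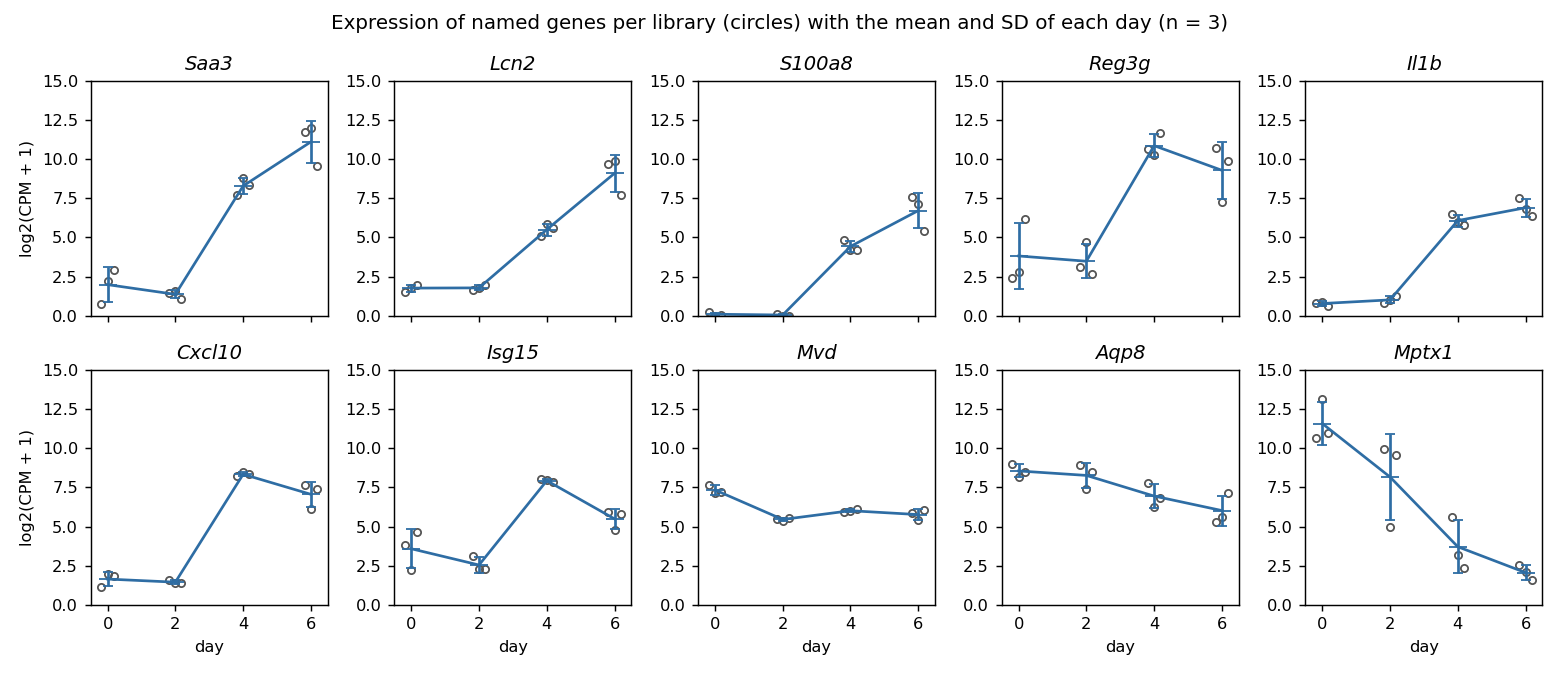
log2(CPM + 1) of 10 genes (y axis) by day (x axis), with circles for the 3 libraries of a day and lines for the mean ± SD. Saa3 rose from a mean of 3.72 CPM at day 0 to 2790 CPM at day 6, Mvd was at its lowest at day 2 with a mean of 42.9 CPM, and Isg15 stood lower at day 6 than at day 4.

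Day 4 was compared with day 2 to place the onset of the changes. The interferon, chemokine and neutrophil genes that were high at day 4 rose after day 2. All 35 interferon response genes rose (35 adjusted over the list alone). Iigp1 stood at 6.52 ± 0.46 and Ifi44 at 5.57 ± 0.31, and camera gave adjusted p = 6.48e-26 (adjusted p = 0.391 with an estimated correlation). Of 14 neutrophil genes 13 rose (13 adjusted over the list alone; camera adjusted p = 4.28e-09, adjusted p = 0.391 with an estimated correlation). Proliferation genes rose in 23 of 26 cases (24 adjusted over the list alone), with a median of 1.65 relative to all genes (camera adjusted p = 1.25e-07, adjusted p = 0.481 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase (2.74 ± 0.37, adjusted p = 0.000213), and the replication licensing gene Mcm3 (2.15 ± 0.26, adjusted p = 9.3e-05) were among them. The cholesterol list had 9 of 22 genes higher and Tm7sf2 lower (9 and 1 adjusted over the list alone), and camera made no call (adjusted p = 0.0503). The 9 became 14 without day 6 replicate 2, 5 without day 2 replicate 2 or day 4 replicate 1, and 4 without day 2 replicate 1 or day 4 replicate 3. Arntl (-1.15 ± 0.16, adjusted p = 0.000253) and its partner Npas2 (-1.59 ± 0.21, adjusted p = 0.000174) fell. Smooth muscle genes fell in 10 of 16 cases (10 adjusted over the list alone). Actg2 stood at -2.28 ± 0.25, and camera gave adjusted p = 3.61e-05 (adjusted p = 0.438 with an estimated correlation). Their count was 5 or 6 without any library of day 2 or day 4 except day 4 replicate 2. Mep1a, a brush border protease (-3.58 ± 0.31, adjusted p = 1.11e-05), Slc26a3 (-1.58 ± 0.29, adjusted p = 0.00178) and Car1 (-1.68 ± 0.41, adjusted p = 0.00896) fell too. Of the 187 genes named in this comparison, 147 kept their call whichever library was left out. Muc2 (-0.88 ± 0.30, adjusted p = 0.0435) lost its call in 8 fits (0.144 without day 4 replicate 1) and Acta2 (-0.90 ± 0.31, adjusted p = 0.0443) in 8 (0.162 without day 4 replicate 1).

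Day 6 was compared with day 4 to see what continued to change. Some T cell, B cell and neutrophil genes rose, and some genes induced by interferon fell. Gzmb rose by 2.72 ± 0.25 (adjusted p = 0.00157), the inhibitory receptor Ctla4 by 1.96 ± 0.29 (adjusted p = 0.00637) and the B cell attractant Cxcl13 by 3.51 ± 0.47 (adjusted p = 0.00462). The antiviral GTPase Mx1 fell (-2.93 ± 0.33, adjusted p = 0.00238), as did Ifit3 (-2.55 ± 0.36, adjusted p = 0.00521), Ifi44 (-2.42 ± 0.31, adjusted p = 0.00441) and the ubiquitin-like Isg15 (-2.45 ± 0.51, adjusted p = 0.0279). Trpm5 (-2.69 ± 0.18, adjusted p = 9.28e-05), Gcg (-2.16 ± 0.27, adjusted p = 0.00403) and Muc2 (-2.15 ± 0.30, adjusted p = 0.00521) fell.

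T cell genes rose from day 4 to day 6 in 13 of 19 cases (17 adjusted over the list alone), with a median of 1.35 (camera adjusted p = 1.32e-16, adjusted p = 0.221 with an estimated correlation). B cell genes rose in 5 of 9 (7 adjusted over the list alone). Ighd stood at 1.29 ± 0.21 and Cd79b at 1.22 ± 0.21, and camera gave adjusted p = 1.24e-07 (adjusted p = 0.0648 with an estimated correlation). Neutrophil genes had 6 of 14 higher and Slfn4, also interferon-inducible, lower (9 and 1 adjusted over the list alone). Il1r2 stood at 2.94 ± 0.32 and Retnlg at 2.52 ± 0.33, and camera gave adjusted p = 1.51e-07 (adjusted p = 0.4 with an estimated correlation). Monocyte and macrophage genes had 7 of 23 higher (17 adjusted over the list alone). Trem2 stood at 1.63 ± 0.19, and camera gave adjusted p = 9.97e-11 (adjusted p = 0.39 with an estimated correlation). Of 35 interferon response genes 11 fell (18 adjusted over the list alone), with a median of -0.84 (camera adjusted p = 1.78e-15, adjusted p = 0.39 with an estimated correlation, fry adjusted p = 0.0447). Glucocorticoid response genes rose in 8 of 14 cases (12 adjusted over the list alone). Lcn2 stood at 3.60 ± 0.45, Mt2 at 2.57 ± 0.39 and Sgk1 at 1.83 ± 0.25, and camera gave adjusted p = 4.15e-13 (adjusted p = 0.18 with an estimated correlation). Enteroendocrine genes fell in 6 of 16 cases (10 adjusted over the list alone; camera adjusted p = 7.21e-08, adjusted p = 0.0648 with an estimated correlation). Mucin and glycosylation genes fell in 5 of 24 (8 adjusted over the list alone). Muc6, Muc1 and Muc4 (-2.22 ± 0.36, -1.75 ± 0.28 and -1.72 ± 0.37) were among them, and camera gave adjusted p = 6.33e-08 (adjusted p = 0.39 with an estimated correlation). No proliferation gene passed by limma (21 lower at an unadjusted p under 0.05, 20 lower adjusted over the list alone), and the list's median was -1.03 (camera adjusted p = 2.11e-12, adjusted p = 0.406 with an estimated correlation). The size of that fall leaned on day 6 replicate 2, whose proliferation score was 4.22. Replicates 1 and 3 of day 6 scored 5.91 and 5.85, and the day 4 libraries 6.48, 6.03 and 6.38. The claudins Cldn1 (1.55 ± 0.26, adjusted p = 0.0109) and Cldn4 (-1.61 ± 0.25, adjusted p = 0.00791) moved apart. List counts were smaller without single libraries of day 4, with 5 T cell, 4 interferon response and 3 monocyte and macrophage genes without replicate 1 or replicate 3. Without replicate 2 of day 4 they were 8 T cell and 6 interferon response genes. B cell genes were 1, 2 and 3 without replicates 1, 2 and 3 of day 4 and 2 without day 6 replicate 1. Neutrophil genes were 3 without day 4 replicate 2, day 4 replicate 3 or day 6 replicate 1, and glucocorticoid genes 5 without day 4 replicate 1, day 4 replicate 3 or day 6 replicate 1. Mucin and glycosylation genes were 3 without any library of day 4, and monocyte and macrophage genes 4 without day 6 replicate 1. Without day 6 replicate 3, 11 neutrophil and 18 monocyte and macrophage genes were higher and 10 enteroendocrine, 11 mucin and glycosylation and 15 proliferation genes lower.

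These counts depended on single libraries and on the fit. They were 73 higher and 54 lower without day 4 replicate 1, 160 and 53 without day 4 replicate 2, and 73 and 42 without day 4 replicate 3. They were 132 and 86 without day 6 replicate 1, 178 and 100 without day 6 replicate 2, and 1470 and 780 without day 6 replicate 3. Fitting only days 4 and 6, limma called 0 genes, with 1937 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0503, while over all 4 days edgeR called 315 higher and 146 lower and DESeq2 839 and 505. Of the 65 genes named here 32 kept their call whichever library was left out, Gzmb, Mx1, Ifit3, Ifi44, Trpm5, Muc2, Gcg, Cxcl13, Ctla4, Il1r2 and Lcn2 among them. Isg15 lost it in 5 fits (adjusted p = 0.117 without day 4 replicate 1), S100a8 (2.29 ± 0.43, adjusted p = 0.019) in 3 (0.088 without day 4 replicate 3) and Saa3 (2.82 ± 0.64, adjusted p = 0.0399) in 9 (0.175 without day 4 replicate 1). Slfn4 (-2.88 ± 0.49, adjusted p = 0.0124) lost it in 2 (0.0623 without day 4 replicate 1) and Cldn1 in 1 (0.0563 without day 4 replicate 3). Muc6 lost it in 1 (0.0532 without day 4 replicate 1), Muc4 in 9 (0.136 without day 4 replicate 1) and Cd79b in 1 (0.0651 without day 4 replicate 1).

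Genes called at day 4 were largely called at day 6 as well. Of the 3225 higher genes 2343 (72.7%) were higher at day 6 and 1 was lower, and of the 1833 lower genes 1392 (75.9%) were lower and 4 higher, where independent lists of these sizes would share 758.3 and 227.4. Of the 31 genes lower at day 2, 27 were lower at day 4 and 27 at day 6 (3.7 and 3.8 for independent lists). Of the 18 higher at day 2, 5 were higher and 8 lower at day 4. The fold changes of days 4 and 6 correlated across genes with r of 0.88, with a covariance of 0.755. In 50 simulations of unchanged groups, with a simulated day 0 group shared by the comparisons, the values were 0.5 and 0.033. For day 2 the real values were 0.23 with a covariance of 0.081 against day 4 and 0.3 with 0.119 against day 6. Both correlations lay below the simulated 0.5, and both covariances above the simulated 0.033. The 3 day 0 libraries were not split between comparisons, so part of the excess over independent lists may come from the shared controls. The simulations cannot size that part: no gene changed in them, so almost no calls were there to be shared (at most 0.02 on average).

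In mm10, Zbtb16 lies on chromosome 9 from 48654297 to 48836222, Arntl on chromosome 7 from 113207465 to 113314126, and Mvd on chromosome 8 from 122433601 to 122443422. Insig1 lies on chromosome 5 from 28071363 to 28078662, Hmgcs1 on chromosome 13 from 119690379 to 119708260 and Lss on chromosome 10 from 76531588 to 76557138. Reg3b and Reg3g lie on chromosome 6 from 78370657 to 78373466 and from 78466269 to 78468872, and Cxcl10 and Cxcl5 on chromosome 5 from 92346638 to 92348889 and from 90759360 to 90761624. Saa3 lies on chromosome 7 from 46711998 to 46715700, Lcn2 on chromosome 2 from 32384633 to 32388252, and S100a9 on chromosome 3 from 90692632 to 90695721. Mmp3 lies on chromosome 9 from 7445822 to 7455975, Ang4 on chromosome 14 from 51763878 to 51773590, Clca1 on chromosome 3 from 145003817 to 145032776 and Mptx1 on chromosome 1 from 174330518 to 174332873. Each value sums reads over a whole gene, and all of these genes are protein coding. Of the genes named, Lss, Gli1, Ciart, Il1b, Timp1, Cxcl10, Sult1a1, Trpm5, Tgtp1, Ciita, Il18bp, Synm, Pfkfb3, Tm7sf2, Sycn, Cx3cr1, Gbp4, Cebpd, Acsm3, Muc4 and Dusp1 overlap another gene in the annotation, so their reads and those of the overlapping gene cannot be told apart without the strand setting. The exceptions are Tm7sf2, Gbp4, Tgtp1 and Cx3cr1, for which an overlapping gene lies on the same strand and that setting would not separate the reads. The paralog groups of Reg3, Clca, Gsdmc, Cyp2c, Ces2, Tgtp, Mptx and Ang genes may exchange reads, so the split of values within each group is uncertain.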

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

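The tests of day 6 replicate 2 and the counts over other splits of the libraries were written down only after the results they measure had been seen.

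Of the 8 genes called higher at day 2 and lower at day 4 than at day 0, 4 were among the largest rises of day 2 and stood out, so the 2 days moved in opposite directions against the same reference. The fall between those days follows from how the genes were chosen, after their values were seen, so only its size is given. Between day 2 and day 4 the log2 fold change was -2.44 for Sgk1, a kinase induced by aldosterone and glucocorticoids that activates epithelial sodium transport. The efflux pump gene Abcb1a stood at -2.87, the alpha-2A adrenergic receptor gene Adra2a at -2.34 and Kbtbd11 at -2.01. From day 4 to day 6 Sgk1 stood at 1.83 ± 0.25, a size that the choice of a low day 4 also favours. The day 2 calls of Sgk1, Abcb1a and Adra2a were lost when single libraries were left out, with adjusted p of up to 0.134 without day 2 replicate 3, and 0.0937 and 0.192 without day 2 replicate 2.

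Day 6 replicate 2 lay apart from the other day 6 libraries on the second principal component. A shallow library was argued against, since it held 38.2 M reads, inside the range of the others. A larger share of muscle wall in the sample would raise wall markers, and its smooth muscle score was 0.67 above the higher of the other 2 libraries. All 3 wall lists were highest in it, and 3 of 5 epithelial lists were lowest. A different piece of tissue and a stronger loss of epithelium cannot be told apart, because both lower the epithelial share, and no second piece of the same colon was analysed here.

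For each comparison of 3 libraries with 3, the 10 splits of the 6 libraries are too few for a share under 0.05. Only 1 split, the real one, reached the real count in each. The real counts were 49, 5058, 5476, 5180 and 434 genes for day 2, day 4 and day 6 against day 0, day 4 against day 2 and day 6 against day 4, and the highest of the other splits gave 2, 1, 5, 1 and 0. For the 6550 genes of the F test over the 4 days, 1 of 100 splits of the 12 libraries, the real one, gave as many, and the highest other gave 105. That argues against chance only if the libraries are independent samples, which the labels do not state.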

How the results depend on the processing

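Array weights gene by gene, fits without 2 libraries and rescaling without ribosomal and mitochondrial RNA were chosen after seeing the data. The planned array weights did not converge and gave no value here. Gene by gene, weights ran from 0.139 to 4.7. Every weighted count exceeded the unweighted one: 2436 higher and 2162 lower at day 2, 6182 and 3517 at day 4 and 6536 and 3414 at day 6. From day 2 to day 4 they were 5406 and 3654, from day 4 to day 6 they were 2482 and 1695, and 5144 and 2711 were shared by days 4 and 6. The F test gave 12549 genes. The cause was not tested.

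Counts of genes stayed within 1.5 times of those reported under pseudocounts of 0.5 and 5, no filter on low values, median-of-ratios scaling, moderation without trend and robust, edgeR, and rescaling without ribosomal and mitochondrial RNA. With a mean of at least 5 CPM, which tests fewer genes, 17 were lower at day 2 and 144 higher from day 4 to day 6. Quantile normalization gave 2920 lower at day 6. DESeq2 gave 190 higher and 350 lower at day 2, 2970 lower at day 4, 2939 lower at day 6, 2236 lower at both days 4 and 6, and 839 higher and 505 lower from day 4 to day 6. The cause of these moves was not tested. Fits of only the 2 days compared, with their variance alone, gave 171 higher and 211 lower at day 2 and 1899 and 986 at day 6. Fewer samples alone would not raise the day 2 counts. These fits gave 2979 lower from day 2 to day 4 and 901 lower at both days 4 and 6. From day 4 to day 6 limma then called 0 higher and 0 lower, with 1937 genes at an unadjusted p under 0.05. Without both day 0 replicate 1 and day 6 replicate 2, 92 were higher and 226 lower at day 2 and 192 higher from day 4 to day 6.

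Leaving out 1 library at a time, day 2 had 4 to 206 higher and 9 to 351 lower genes, both highest without day 6 replicate 2. From day 4 to day 6 there were 73 to 1470 higher and 42 to 780 lower, both highest without day 6 replicate 3. The other gene counts stayed within 1.5 times. List calls by camera at day 2 ran from 10 (without day 0 replicate 2) to 21 (without day 0 replicate 1). The cause was not tested.

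With an estimated correlation, camera called 0 lists in each of the 5 comparisons, against 17, 25, 32, 23 and 27 with the preset one. Of 225 list results 124 lost their call and 101 stayed on their side of the threshold, and fry, which asks another question, lost 43 and gained 13. It called 3 lists at day 2 and 12 from day 4 to day 6. For inflammasome and gasdermin genes at day 6, with a median log2 fold change of -0.083 and no call by camera, fry gave the other direction (adjusted p = 0.0394). Camera's direction turned without day 6 replicate 2 for 4 list results. The median for proliferation at day 6 was then 0.292 (adjusted p = 0.0296), and -0.56 at its lowest, without day 6 replicate 1. From day 4 to day 6 the median for fatty acid and ketone oxidation was then 0.201 (0.0179) and for respiratory chain subunits 0.221 (0.000153), against lowest values of -0.184 and -0.258 without day 6 replicate 3. For enteric neurons and glia it was 0.011 (0.707), against a highest value of 0.84 without day 6 replicate 3. Of 720 values of named genes, 23 lost their call under median-of-ratios scaling, 26 under quantile normalization, 12 with a pseudocount of 5 and 2 with 0.5. COX1 from day 2 to day 4 turned to 0.226 under quantile normalization (adjusted p = 0.583). The cause was not tested.

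Replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated above 0.1 in 6 of 18 pairs, from -0.21 to 0.64, with a median of 0.04 against -0.01 for different numbers. With the replicate number as a block, 23 genes were higher and 37 lower at day 2, and 305 and 161 from day 4 to day 6, and every gene count stayed within 1.5 times. The block ended 14 calls of named genes and added 1, and ended 3 list calls and added 8.

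Sequencing depth limits only genes near the filter. In simulated data limma recovered 1 of 50 genes at 1.5-fold and 19 of 50 at 2-fold, so smaller changes can be missed.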

Other observations

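The tests of the cholesterol and interferon patterns were chosen only after the results were seen, gene sets of the clock and of the interferon types included, except the test of the interferon change on single libraries, which was written beforehand.

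Some marker genes of the gut wall and of lesser immune types changed as well. Neuron and glia genes of the gut wall rose in 7 of 20 cases at day 6 (14 adjusted over the list alone). Gfap, a marker of reactive glia (2.97 ± 0.33, adjusted p = 4.7e-05), and the neuropeptide genes Tac1 (1.75 ± 0.37) and Vip (1.69 ± 0.42) were among them, and camera gave adjusted p = 0.00222 (adjusted p = 0.551 with an estimated correlation). At day 4 they rose in 4 (3 adjusted over the list alone; camera adjusted p = 0.0562), with 12 without day 6 replicate 2, 9 without day 6 replicate 3, 2 without day 0 replicate 3 and 1 without day 4 replicate 2. The day 6 count was 18 without day 6 replicate 3. Plasma cell genes were still lower at day 6 in 7 of 10 cases (9 adjusted over the list alone; camera adjusted p = 4.1e-06, adjusted p = 0.247 with an estimated correlation). B cell genes were split, with Cd22 (1.16 ± 0.20) and Ighd (0.94 ± 0.21) among 5 of 9 higher at day 6 and Cd79a lower, a call lost without day 6 replicate 1 (adjusted p = 0.137). Adjusted over the list alone, 6 were higher and 2 lower, and camera made no call (adjusted p = 0.431). Of 4 mast cell and eosinophil genes, Il5ra, the receptor that eosinophils use for interleukin 5, rose at day 4 (2.86 ± 0.44, adjusted p = 0.000613) and day 6 (1.58 ± 0.44, adjusted p = 0.0171), a call lost at day 6 without day 0 replicate 1 (0.0745). Siglecf fell at day 6 (adjusted p = 0.00208), and adjusted over the list alone 2 of the 4 were higher and 1 lower. Among markers of interstitial cells of Cajal, the pacemakers of the gut, Ano1 fell (-1.22 ± 0.28, adjusted p = 0.00538) and Gja1 rose (1.90 ± 0.33, adjusted p = 0.00103) at day 6, in a list of 5 (1 and 1 adjusted over the list alone; camera adjusted p = 0.653). Smooth muscle genes fell in 7 of 16 cases at day 6 (7 adjusted over the list alone). Synm stood at -1.59 ± 0.39, and camera gave adjusted p = 0.00276 (adjusted p = 0.459 with an estimated correlation). The count was 11 without day 6 replicate 2 and 4 without day 0 replicate 3, day 6 replicate 1 or day 6 replicate 3. The adipose genes Fabp4 (1.68 ± 0.42) and Lpl (0.96 ± 0.20) rose at day 6 in a list of 5 (2 adjusted over the list alone; camera adjusted p = 0.709).

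Of 18 oxidative stress genes 7 rose at day 6 and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.151). The haem oxygenase Hmox1 stood at 3.08 ± 0.35 and Mt1 at 2.77 ± 0.39 against the quinone reductase Nqo1 at -1.15 ± 0.36 (adjusted p = 0.11 without day 0 replicate 1). Unfolded protein response genes had 8 of 21 higher and Herpud1 lower at day 6 (8 and 1 adjusted over the list alone; camera adjusted p = 0.39), with the chaperone Hspa5 at 0.76 ± 0.22 (adjusted p = 0.0675 without day 0 replicate 3). At most 3 were higher without day 0 replicate 1, day 0 replicate 3 or day 6 replicate 1. Tight and adherens junction genes had 6 of 24 lower and Cldn1 higher at day 6 (6 and 1 adjusted over the list alone). The pore-forming claudin Cldn15 stood at -2.21 ± 0.57 and Ocln at -1.23 ± 0.25, and camera gave adjusted p = 0.00153 (adjusted p = 0.474 with an estimated correlation), and 15 were lower without day 6 replicate 3. Inflammasome and gasdermin genes went both ways, 5 of 16 higher and 4 lower at day 6 (5 and 4 adjusted over the list alone; camera adjusted p = 0.844), since Nlrp3 (3.44 ± 0.26) and Il18bp (3.89 ± 0.24) rose and Gsdmc2 (-4.27 ± 0.54) fell. Of 33 subunits of the respiratory chain 5 fell at day 6 (3 adjusted over the list alone). Ndufa1 stood at -0.79 ± 0.13, and camera gave adjusted p = 1.62e-07 (adjusted p = 0.449 with an estimated correlation). The count ran from 1 without day 0 replicate 1 to 27 without day 6 replicate 3. Mitochondrially encoded genes had 2 of 13 lower (2 adjusted over the list alone; camera adjusted p = 0.009, adjusted p = 0.474 with an estimated correlation, and 0.0641 without day 0 replicate 2), with ND3 at -1.66 ± 0.26. Their count was 6 without day 0 replicate 1 and 1 without day 0 replicate 2, day 0 replicate 3, day 6 replicate 1 or day 6 replicate 2. In the apoptosis list Fas rose (1.91 ± 0.16) and Bbc3 fell (-0.93 ± 0.22) at day 6, with 3 of 16 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.578). Immediate early and dissection-related genes rose in 9 of 17 cases at day 6 (9 adjusted over the list alone). Hsph1 stood at 1.97 ± 0.31, and camera gave adjusted p = 0.00494 (adjusted p = 0.247 with an estimated correlation).

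Cholesterol synthesis genes were lower at days 2, 4 and 6 than at day 0. Scaling between libraries was argued against, as the median nearest to 0 over the 3 days and 2 scalings was -1.01, and so was a loss of epithelial cells at day 2, where the median of the junction list lay 1.37 above that of the cholesterol list, more than the SD of 0.3 among the junction list's members. An index of 13 clock genes, which rises with Arntl-type and falls with Per-type genes, differed from day 0 by 1.92 at day 2, 1.25 at day 4 and 1.85 at day 6 (exact two-sided permutation p of 0.1 each, the smallest that 3 against 3 can give), so a shift of clock phase may account for part of the drop at day 2. At days 4 and 6 the index was displaced by up to 0.96 of its day 2 value (without Nfil3, which cytokines also induce, it differed from day 0 by 0.75 and 1.02, against 1.86 at day 2) and the mean of its 9 Per-type genes differed from day 0 by -0.74 and -0.96, against -0.87 at day 2, but the mean of the other 3 genes, Arntl, Clock and Npas2, was displaced by at most 0.06 of its day 2 value, which argues against the same clock phase as at day 2. Harvest times are not given in the sources used here, so another clock phase and an effect of DSS on sterol synthesis cannot be told apart at days 4 and 6. A loss of epithelial cells was not tested at days 4 and 6 and stays open there too. The junction score then differed from day 0 by -0.01 and -0.45, and the goblet cell score by -1.39 and -2.34. At day 2 a clock shifted by treatment, a different hour of harvest and a loss of crypt cells all stay open.

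The interferon response fell from day 4 to day 6 in 1 part of the list. Scaling was argued against, since the median nearer to 0 under 2 scalings was -0.79, and so was a single library, since the highest median over 6 fits without 1 library was -0.72 (without day 4 replicate 2). Dilution by cells that express none of these genes would lower all members alike. The 16 genes driven mainly through ISGF3, the complex of type I and III interferon signalling, changed by -1.99 in mean score. The 17 genes of the interferon gamma type changed by -0.32, a change of -1.67 in the difference with a larger SD of 0.3 (exact two-sided permutation p = 0.1, the smallest possible). Of the ISGF3 genes 10 were lower and of the interferon gamma type 0 by limma, with median log2 changes of -2 and -0.26. That argues against such dilution only. Added cells that express genes of the interferon gamma type could give the same split, so a change of cell mix stays open. The T cell score rose by 1.33 and the monocyte and macrophage score by 1.03 between these days. A hypothesis is that type I or III interferon signalling had declined by day 6 while interferon gamma signalling persisted, which may fit the rise of Gzmb and Ctla4 but was found and tested on the same data.

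Genes of other tissues and regions changed as well. Pancreas-type Cela1 fell at day 4 (-2.45 ± 0.40, adjusted p = 0.000928) and day 6 (-2.75 ± 0.40, adjusted p = 0.000349), with the secretory genes Sycn and Clps lower at day 6 as well. The small intestine marker Fabp2 fell at day 4 (-2.01 ± 0.35, adjusted p = 0.00142) and day 6 (-2.59 ± 0.35, adjusted p = 0.000218). Of 5 genes in its list 2 were lower at day 4 (2 adjusted over the list alone; camera adjusted p = 0.0982, and 1 lower without day 0 replicate 3, day 4 replicate 1 or day 4 replicate 2). At day 6 the count was 1 (1 adjusted over the list alone; camera adjusted p = 0.0668), or 2 without day 6 replicate 3. The skeletal muscle list gave camera adjusted p of 0.00666 at day 2 (0.867 with an estimated correlation) with none of 7 genes past the threshold by limma, adjusted over the list alone or at an unadjusted p under 0.05, and 0.222 without day 0 replicate 2.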
